A study of Mus musculus with 54 samples.

How the data were processed

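RNA from the mouse small intestine was measured by sequencing of polyadenylated RNA with strand-specific libraries. The samples came from 3 sections (duodenum, jejunum and ileum) of females on day 7 of lactation, virgin females of the same age and virgin males, with 6 libraries in each of the 9 groups. The submitters' processing notes name GRCm38, FastQC 0.11.5, STAR 2.7.7a and DESeq2 1.34.0 without saying what each was used for, and the labels do not name the gene annotation. The deposited files hold, for each library, raw read counts per gene symbol in the layout of STAR's gene count output, with no scaling or filter by the authors. Each file has 4 leading entries for reads assigned to no gene and 25229 gene symbols. Column 4 was used, the strand that a directional kit of this kind gives: it held between 97.9% and 98.6% of the stranded gene reads in every library. Reads that fitted several places are not in the gene counts, so members of families with near-identical sequence are undercounted.

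Of the 25229 symbols, 24366 matched the GENCODE M21 annotation of GRCm38, 24321 of them once, and 25031 matched a RefSeq gene table. Coordinates are from GENCODE on GRCm38, counted from 1. None of the 13 listed mitochondrially encoded genes was among the symbols, nor were the constant-region genes of immunoglobulins and T cell receptors, so neither set was analysed here.

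Genes were tested with edgeR 4.0.16 (quasi-likelihood F test) under R 4.3.3. Genes were kept by edgeR's expression filter (minimum count 10, minimum total 15), libraries were scaled by the trimmed mean of M values (TMM), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05. Lactating females were compared with virgin females, and virgin females with virgin males, within each section in a fit of that section's 18 libraries. Sections were compared in a fit of the 18 virgin female libraries. Differences of the lactation effect between sections were contrasts in a fit of the 36 female libraries, and the difference of the sex effect between sections was an F test over 36 libraries. The labels do not state that libraries with the same number came from 1 animal, so no animal term was fitted. Levels are read counts scaled to library size in the usual unit CPM, computed within the fit of the comparison, given as mean ± SD, and log2 fold changes are given ± SE. Exceptions are some values of single libraries. Those of Alb, Lct, Sis, Pdx1, S100g, Trpv6 and Cyp2d34 in the text of the Results are scaled to library totals alone. Those of samples far from their group are scaled by TMM over all 54 libraries. The same library therefore has different values in different passages.

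Before the data were examined, 41 lists of genes were written for digestion and transport, epithelial and other cell types, neighbouring tissues, immune responses, metabolism and growth. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), 2-sided, with the inter-gene correlation preset at 0.01 and with an estimated correlation, and with fry, which asks whether a list's genes move one way on balance. List p-values were adjusted over the lists. Counts of called members are given as adjusted over all genes and as adjusted over the list alone. The rule for named genes was fixed at the same time. It took Slc5a1, Slc5a4a, Slc5a4b, Lgr5, Olfm4, Mki67, Trpv6, S100g, Fgf15, Prlr, Xist and Ddx3y in every comparison. It added the largest rises and falls among called genes with a mean log2 CPM of at least 1, a symbol other than a Gm, Rik or bare identifier name, and groups that did not overlap: 10 each way for lactation, 6 for sex and 8 for sections. For differences between sections it took 5 called genes of each sign with that mean log2 CPM. For each list it took up to 4 called members with the largest change, or the 2 with the highest level where none was called. A fold against a group with no reads is a lower bound computed at 3 counts over the group.

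Alternatives were median-of-ratios size factors, library totals alone, DESeq2 1.42.0, limma-voom, no count filter, a filter of CPM above 1 in at least 6 libraries, a block for the library number, a fit of the 2 compared groups only, a fit of all 54 libraries, a threshold of 1 on the absolute log2 fold change, and leaving out each library in turn. After the data were seen, each comparison was also made without 2 libraries whose transcripts differ from their labelled section, within the fits above and in 1 fit of the other 52 libraries. The reported values use all libraries as labelled, with the values without the 2 libraries beside them. The fits without the 2 libraries were tested on simulated data with 200 genes changed (the fits as labelled were not): a 2-fold change was recovered for 70.1% of genes in the duodenum, 88.1% in the jejunum and 91.0% in the ileum, and a 1.5-fold change for 37.3%, 59.7% and 62.7%. The changed genes were drawn from those with a mean CPM above 1. Counts were simulated for each gene independently, so differences between libraries that many genes share were left out. The shares therefore do not measure recovery in the real fits. In 100 random regroupings per comparison (fixed seed), libraries were reassigned to the compared groups and the fit repeated. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Unmapped reads and reads between genes were used only as library measures, and splicing, transposable elements and sequence variants were not analysed here. The values of 1 gene that the rule names are not reported here.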

Results

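The small intestine of lactating mice was compared with that of virgin females and virgin males in 3 sections: the duodenum next to the stomach, the jejunum, and the ileum at the far end. Each section had 6 libraries from females on lactation day 7, 6 from age-matched virgin females and 6 from virgin males, 54 in all. The series asks how the maternal gut grows through pregnancy and lactation, and this part compares gut sections. Gene reads per library ran from 18479722 to 27604041, and 15791 to 17920 genes had reads. Between 19.5% and 31.7% of reads were assigned to no gene. The labels do not say that every library came from a separate animal, so the p-values measure the spread between samples, and the lower bounds on folds cover counting error only.

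Genes of the section set most libraries apart, and 2 libraries did not carry the transcripts of their labelled section. The library labelled lactating female duodenum 3 had 109900 CPM of Alb, the liver's serum albumin, against at most 176 CPM in the other libraries. Of 30 listed liver genes, 27 were highest in it, and they took 23.3% of its gene reads (at most 2.22% elsewhere). It had 0.0429 CPM of the lactase gene Lct and 0.129 CPM of the sucrase-isomaltase gene Sis, where the other lactating duodenum libraries had 1615 to 3270 and 2478 to 4445. The library labelled lactating female jejunum 3 lay near the duodenum: over 75 genes that differ between these sections in males, it stood 78.1% of the way from the jejunum level to the duodenum level. The other female jejunum libraries stood at -5.07% to 13.2% and the female duodenum libraries at 86.4% to 116%. Lactation results in the duodenum and jejunum are given with all libraries as labelled or without these 2, and for most in both ways.

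**Figure D1:**
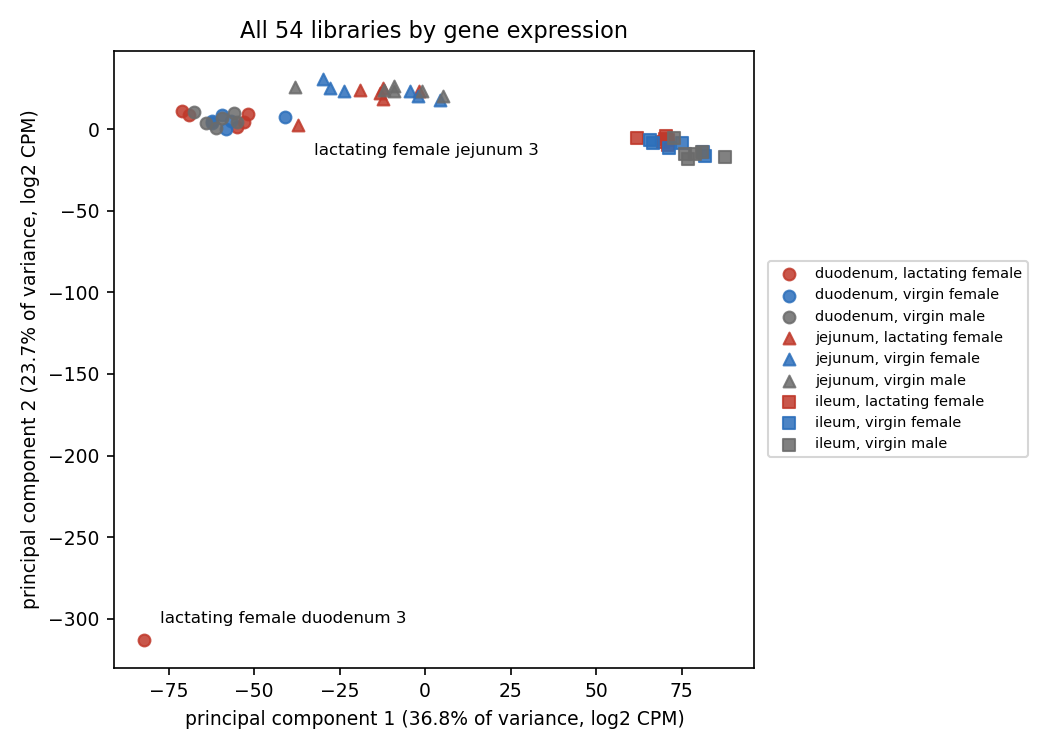
Principal component 1 (36.8% of the variance, horizontal) and component 2 (23.7%, vertical) of log2 CPM for the 54 libraries, with colour for the group of animals and marker shape for the section. The library labelled lactating female duodenum 3 sits alone at -313 on component 2, and the ileum libraries lie at 61.9 or more on component 1.

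Duodenum, jejunum and ileum of virgin females were compared to ask what distinguishes the sections, with 6 libraries each. The duodenum was marked by Tmprss15, which activates pancreatic trypsinogen at 85.5 ± 40.2 CPM. It was at 0.0443 ± 0.0730 CPM in the jejunum (log2 fold change -10.61 ± 0.53, adjusted p = 3.71e-09 by edgeR) and had no read in the ileum, at least 4240-fold lower. Pdx1, a transcription factor of the duodenum and pancreas, fell from 31.4 ± 19.1 to 0.132 ± 0.0556 CPM at the same step. Lct, which digests milk sugar, was at 4084 ± 534 CPM in the jejunum and 0.353 ± 0.178 in the ileum (-13.47 ± 0.41, adjusted p = 6.76e-15). Fabp6, the ileal bile acid binding protein, rose from 2.89 ± 5.30 CPM in the jejunum to 3473 ± 1569 in the ileum (10.22 ± 0.86, adjusted p = 1.37e-08). Slc10a2, the bile acid importer, rose from 5.05 ± 4.51 to 837 ± 208 (7.37 ± 0.42). Fgf15, the hormone by which the ileum restrains bile acid synthesis in the liver, had no read in the duodenum and stood at 38.5 ± 36.2 CPM in the ileum, at least 1860-fold higher. That mean rests in part on virgin female ileum 5. In the fit of the ileum libraries it had 118 CPM, and the other virgin females had 3.57 to 53.0.

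From duodenum to jejunum, genes of iron uptake were among those that fell: Slc40a1, the iron exporter, changed by -4.42 ± 0.45. Slc46a1, which carries heme and folate, went from 488 ± 102 to 123 ± 25.6 CPM (adjusted p = 1.87e-06). The iron and trace metal list as a whole went both ways, with 5 members up and 6 down of 19 (median 0.05, mean -0.44, camera adjusted p = 0.465). S100g, the calcium carrier of the enterocyte, fell from 71.4 ± 85.5 to 2.77 ± 1.13 CPM (-4.69 ± 0.56). Slc5a8, a transporter of short-chain fatty acids, rose from 0.0287 ± 0.0507 to 114 ± 32.6 CPM (11.76 ± 0.35, adjusted p = 2.44e-14). The patterning gene Hoxc8 went from no read to 4.89 ± 1.99 CPM, at least 236-fold higher. Peptide digestion and transport rose in 20 of 25 members and fell in 1 (the same 20 and 1 adjusted over the list alone; camera adjusted p = 6.90e-10, and adjusted p = 0.626 with an estimated correlation). Fat absorption rose in 19 of 27 and fell in 1 (20 and 1 over the list alone; 9.94e-07, and adjusted p = 0.626 with an estimated correlation). Paneth cell genes rose in 13 of 18 (15 over the list alone; 1.61e-06, and adjusted p = 0.626 with an estimated correlation), among them the defensin gene Defa20 (6.58 ± 0.67). Macrophage genes fell in 17 of 21 (17 over the list alone; 6.67e-06, and adjusted p = 0.626 with an estimated correlation). Interferon response genes fell in 17 of 34 (17 over the list alone; 7.58e-06, and adjusted p = 0.649 with an estimated correlation). Exocrine pancreas genes fell in 8 of 10 and rose in 1 (9 and 1 over the list alone; 3.27e-04, and adjusted p = 0.626 with an estimated correlation). The chymotrypsinogen gene Ctrb1 led them, at 926 ± 899 CPM in the duodenum and 0.112 ± 0.0594 in the jejunum. The pancreas genes made up between 0.204% and 1.64% of gene reads in the virgin female duodenum libraries. They made up 0.143% to 0.414% in virgin female jejunum and 0.244% to 0.49% in virgin female ileum, so the low end in the duodenum was no higher than elsewhere. By Ctrb1, scaled over all 54 libraries, virgin female duodenum 3 had 0.572 CPM and the rest of that group 157 to 2140.

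From jejunum to ileum, all 17 tested genes of sugar digestion and transport fell (17 over the list alone; camera adjusted p = 3.86e-16, and adjusted p = 0.259 with an estimated correlation). They include the fructose and glucose exporter gene Slc2a2 (-9.52 ± 0.40), Slc5a4a (-4.96 ± 0.40), Slc5a4b (-6.01 ± 0.49). Slc5a1, the main sodium-glucose cotransporter, was at 3963 ± 770 CPM in the jejunum and 971 ± 268 in the ileum (-2.03 ± 0.22). Fat absorption fell in 26 of 27 members (26 over the list alone; 1.67e-17, and adjusted p = 0.259 with an estimated correlation), with Fabp1 down from 2841 ± 677 to 5.65 ± 3.21 CPM. Cholesterol synthesis rose in 22 of 25 and fell in 1 (22 and 1 over the list alone; 3.22e-12, and adjusted p = 0.259 with an estimated correlation). Bile acid genes rose in 8 of 11 and fell in 2 (9 and 2 over the list alone; 0.00315, and adjusted p = 0.335 with an estimated correlation). Cell cycle genes rose in 27 of 39 (28 up and 1 down over the list alone; 4.66e-06, and adjusted p = 0.686 with an estimated correlation). Goblet cell genes rose in 14 of 18 (14 over the list alone; 7.44e-04, and adjusted p = 0.686 with an estimated correlation). Fibroblast genes did so in 22 of 27 (25 over the list alone; 2.42e-06, and adjusted p = 0.680 with an estimated correlation). Lgr5, the crypt stem cell receptor, was at 5.25 ± 1.67 CPM in the jejunum and 12.1 ± 1.06 in the ileum (1.21 ± 0.16). Genes of oxidative phosphorylation fell in 49 of 85 and rose in 2 (51 and 2 over the list alone; 2.75e-08, and adjusted p = 0.686 with an estimated correlation). Drug and steroid metabolism fell in 22 of 35 and rose in 5 (23 and 5 over the list alone; 3.18e-06, and adjusted p = 0.680 with an estimated correlation).

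**Figure D2:**
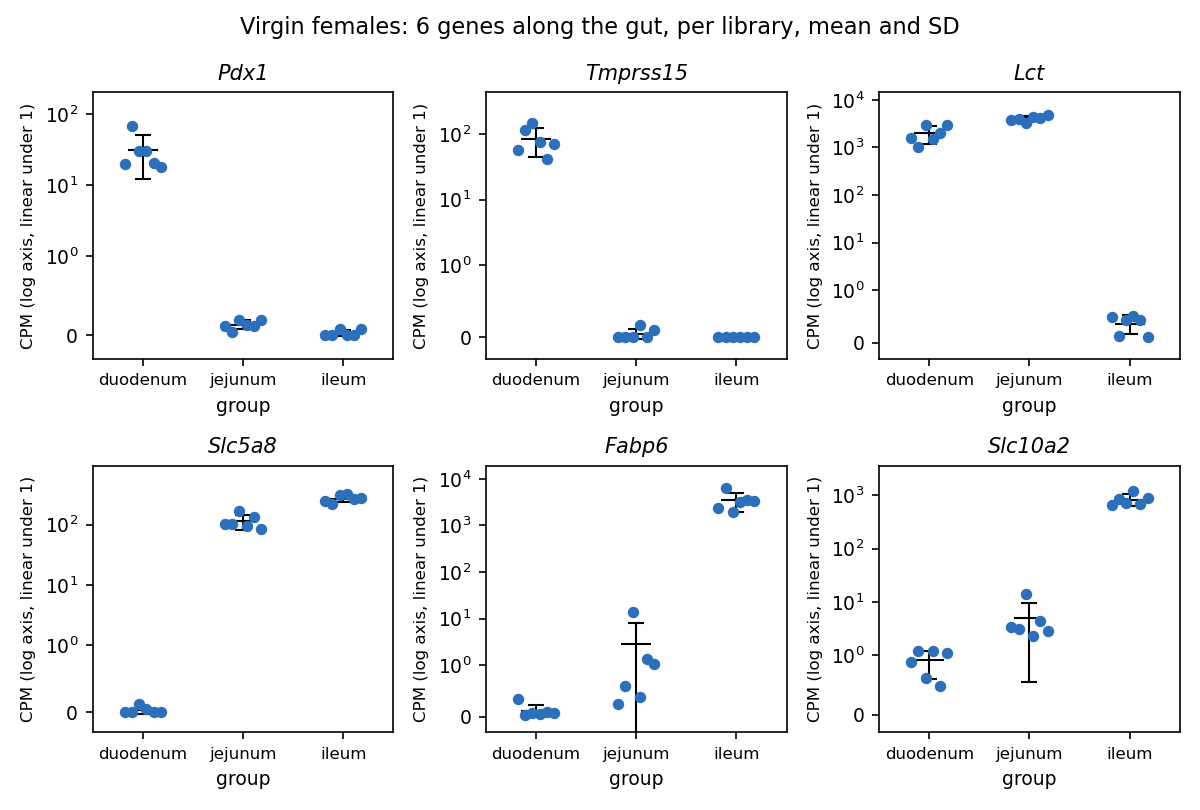
CPM (vertical axis, logarithmic and linear under 1) of 6 section marker genes in virgin female duodenum, jejunum and ileum; points are libraries and bars are the mean ± SD of 6. Tmprss15 averaged 85.5 CPM in the duodenum, Lct 4084 in the jejunum and Fabp6 3473 in the ileum.

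In total, edgeR called 5635 of 15154 genes between jejunum and duodenum (2599 higher in the jejunum, 3036 lower). It called 7271 between ileum and jejunum (3619 higher in the ileum, 3652 lower) and 7130 between ileum and duodenum (3191 higher in the ileum, 3939 lower). Of these, 358 genes rose at both steps along the gut, 467 fell at both, 1260 rose and then fell and 1029 fell and then rose. Directly from duodenum to ileum, 24 of 25 cholesterol synthesis genes rose (24 over the list alone; 2.49e-16, and adjusted p = 0.244 with an estimated correlation). Along the same span, 17 of 23 patterning factors rose and 4 fell (17 and 4 over the list alone; 4.50e-05, and adjusted p = 0.244 with an estimated correlation). Scaling by library totals alone shifted the median of all genes by -0.22, 0.35 and 0.13 log2 in the order above, and by -0.14 for lactation in the duodenum. It changed the splits to 1394 higher and 5650 lower, 8101 and 1731, and 4235 and 2877. The counts above are relative to that median.

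Lactating females were compared with virgin females in each section, the series' main contrast. In the ileum, some genes of sugar, mineral and fat uptake rose in lactation, among them Slc5a4a, S100g and Fabp2. Slc5a4a, of the sodium-glucose cotransporter family, lies on chromosome 10 (76147451 to 76189265, GRCm38). It rose from 6.44 ± 4.19 CPM in virgin females to 37.4 ± 17.6 in lactating females (n = 6 each; log2 fold change 2.54 ± 0.45, adjusted p = 0.00677 by edgeR). Its neighbour Slc5a4b rose by 1.70 ± 0.44 (adjusted p = 0.0489) and Slc2a2 from 0.468 ± 0.393 to 2.56 ± 2.30 CPM (2.46 ± 0.63, adjusted p = 0.0480). Slc2a2 was near the floor, and its lactating mean rests in large part on lactating female ileum 1 and 2, at 6.75 and 3.75 CPM. The other lactating libraries had 0.978 to 1.56 CPM of Slc2a2, meeting the virgin females at 0.0447 to 0.978. S100g, the calcium carrier, rose from 3.79 ± 1.43 to 17.4 ± 16.7 CPM (2.20 ± 0.53, adjusted p = 0.0326). Its lactating mean rests in large part on lactating female ileum 2 and 4, at 40.3 and 37.5 CPM. The other lactating libraries had 4.53 to 7.96 CPM of S100g, overlapping the virgin females at 2.00 to 6.13. Fabp2, an intestinal fatty acid binding protein, rose from 2206 ± 753 to 4317 ± 317 (0.97 ± 0.21, adjusted p = 0.0214). The gasdermin genes Gsdmc2, Gsdmc3 and Gsdmc4, side by side on chromosome 15, fell: Gsdmc3 from 51.3 ± 14.3 to 18.4 ± 6.97 CPM (-1.48 ± 0.26, adjusted p = 0.00656).

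By group, sugar digestion and transport rose in 3 of 17 members and fell in none (9 adjusted over the list alone; camera adjusted p = 1.49e-07, and adjusted p = 0.399 with an estimated correlation). Peptide and amino acid transport rose in 2 of 24 (9 over the list alone; 6.09e-06, and adjusted p = 0.406 with an estimated correlation). Slc6a19, a neutral amino acid transporter, rose by 0.78 ± 0.19 and Slc3a1 by 0.44 ± 0.10. Slc6a18, of the same family as Slc6a19, rose from 6.25 ± 2.65 to 17.9 ± 4.85 CPM (1.51 ± 0.23). Fat absorption rose in 5 of 26 (14 over the list alone; 1.11e-08, and adjusted p = 0.399 with an estimated correlation). Beside Fabp2 these included the fatty acid transporter Slc27a4 (0.65 ± 0.15), Acsl5 (0.63 ± 0.12) and the cholesterol importer Npc1l1 (0.54 ± 0.13). Cholesterol synthesis rose in 3 of 25 (11 over the list alone; 2.65e-10, and adjusted p = 0.399 with an estimated correlation). Among these Sqle went from 222 ± 32.5 to 298 ± 35.8 CPM. Scaled by library totals alone, 0 of these 25 were called by edgeR and their median stayed above 0, at 0.18. The list of calcium and phosphate transport and vitamin D targets rose in 3 of 13 (6 over the list alone, camera adjusted p = 0.00518, and adjusted p = 0.399 with an estimated correlation). Beside S100g these were Slc30a10 (1.37 ± 0.33) and the phosphate transporter Slc34a2 (0.52 ± 0.12). Of the iron and trace metal list, 2 of 19 members rose (3 over the list alone). The zinc importer Slc39a4 went from 445 ± 116 to 897 ± 231 CPM (adjusted p = 0.0125) and the copper importer Slc31a1 rose by 0.90 ± 0.16. That list's median was -0.08 and its mean 0.07, and camera did not call it (adjusted p = 0.160). Villus tip genes rose in 3 of 13 (6 over the list alone; 6.07e-07, and adjusted p = 0.399 with an estimated correlation). Among them the purine enzyme gene Ada went from 182 ± 104 to 448 ± 139 CPM.

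Interferon response genes rose in 8 of 34 (11 over the list alone; camera adjusted p = 1.49e-07, and adjusted p = 0.672 with an estimated correlation). Irf7, a regulator of interferon genes, went from 157 ± 21.6 to 294 ± 54.4 CPM (0.91 ± 0.14, adjusted p = 0.00332). Oas3, Rsad2, Oas2 and Ddx60, which act against viruses, rose by 1.20 ± 0.21, 1.03 ± 0.18, 0.93 ± 0.24 and 0.85 ± 0.20. Drug and steroid metabolism rose in 2 of 32 (4 over the list alone; 0.00219, and adjusted p = 0.678 with an estimated correlation). Outside these groups, the skeletal actin gene Acta1 rose from 47.4 ± 24.6 to 224 ± 121 CPM (adjusted p = 0.0152). Other rises were those of Flvcr2 (2.36 ± 0.39), Dmrt3 (1.59 ± 0.22), Unc93a2 (1.76 ± 0.30), Apol9a (1.66 ± 0.26) and Apol9b (1.33 ± 0.25).

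Genes of enteric neurons and glia fell in 4 of 20 and rose in none (13 over the list alone; camera adjusted p = 2.78e-08, and adjusted p = 0.399 with an estimated correlation). Snap25, of synaptic vesicle release, fell by 0.63 on the log2 scale (SE 0.14). Uchl1 changed by -0.61 ± 0.16, Elavl4 by -0.57 ± 0.14 and Prph by -0.56 ± 0.14. Endothelial genes fell in 1 of 17, Pecam1 (5 over the list alone; 2.06e-04, and adjusted p = 0.399 with an estimated correlation). In the fibroblast list Mmp2 and Postn fell (2 of 27, 3 over the list alone; 0.0204, and adjusted p = 0.678 with an estimated correlation). In the macrophage list Itgam fell (1 of 21 by either adjustment; 0.00305, and adjusted p = 0.678 with an estimated correlation). Patterning factors fell in 2 of 23, Hoxa5 and Hoxb6 (2 up and 6 down over the list alone; 0.0126, and adjusted p = 0.399 with an estimated correlation). Igf1r, the receptor of insulin-like growth factor 1, fell from 33.5 ± 2.87 to 24.2 ± 2.01 CPM (-0.47 ± 0.07, adjusted p = 0.00404), and Igfbp3, which binds that factor, changed by -0.47 ± 0.11. They were 2 of 22 genes of hormone signalling (4 lower over the list alone), a list that camera did not call (adjusted p = 0.281). Ribosomal protein genes had 0 of 75 called by edgeR (0 over the list alone) with a median of -0.17 (0.00107, and adjusted p = 0.767 with an estimated correlation). Cell cycle genes had 0 of 39 (0 over the list alone) with a median of 0.11 (0.00392, and adjusted p = 0.698 with an estimated correlation). Mki67, a marker of dividing cells, was at 143 ± 11.1 CPM in lactating and 135 ± 17.2 in virgin females (0.08 ± 0.10, adjusted p = 0.724). The stem cell genes Lgr5 (0.09 ± 0.09, adjusted p = 0.659) and Olfm4 (0.28 ± 0.14, adjusted p = 0.333) did not pass the test. Nor did Slc5a1 (0.36 ± 0.16, adjusted p = 0.233), the prolactin receptor gene Prlr (0.31 ± 0.13, adjusted p = 0.222) or Fgf15 (14.4 ± 9.94 against 42.8 ± 40.3 CPM, adjusted p = 0.194).

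**Figure D3:**
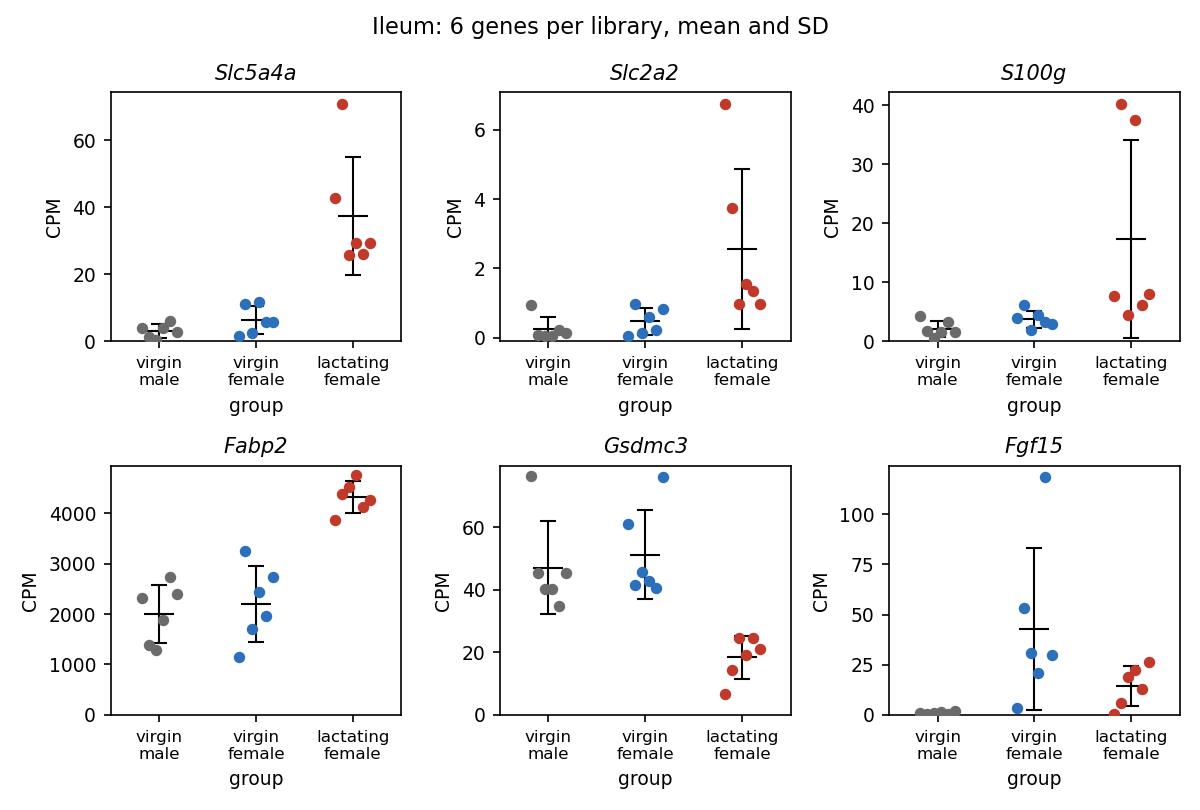
CPM of 6 genes in the ileum of lactating females, virgin females and virgin males; points are libraries and bars are the mean ± SD of 6. Slc5a4a averaged 37.4 CPM in lactating and 6.44 in virgin females, and Gsdmc3 18.4 and 51.3.

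In all, edgeR called 327 of 15106 genes between lactating and virgin ileum, 189 higher and 138 lower in lactation. With library totals alone it called 575, 123 higher and 452 lower. The count moved by more than 1.5 times when 1 library was left out. Without virgin female ileum 1, 2, 3 or 5 it was 112, 1184, 143 or 196, and without lactating female ileum 1, 3 or 6 it was 159, 205 or 173. Of the 56 called genes named by the rule, 26 stayed called in all 12 of these fits, among them Slc5a4a, Flvcr2, Acta1, Slc39a4, Irf7, Igf1r and the 3 gasdermin genes. S100g lost its call in 5, Slc2a2 in 8, Slc5a4b in 9, Sqle in 8, Npc1l1 in 9, Slc6a19 in 8, Slc30a10 and Slc34a2 in 6, Slc27a4 in 5, Slc3a1 and Ada in 2 and Fabp2 in 1. Of the interferon genes Oas2 lost it in 9 and Ddx60 in 7. Of those that fell, Snap25 lost it in 4, Uchl1 in 6, Elavl4 and Prph in 7, Pecam1 in 8, Itgam in 9, Igfbp3 in 7, Hoxa5 in 6, and Hoxb6 and Postn in 4. The highest adjusted p of Fabp2 was 0.0553.

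In the jejunum, Fgf15 and the water channel gene Aqp1 fell in lactation and the thiamine transporter gene Slc19a3 rose. As labelled, Fgf15 fell from 2.51 ± 1.72 CPM to 0.117 ± 0.0986 (n = 6 each; -4.42 ± 0.79, adjusted p = 0.0227 by edgeR). Fgf15 was near the floor in lactation, at 0 to 0.23 CPM per library. It was at 0.316 CPM in virgin female jejunum 1 and at 0.0458 to 1.48 in virgin males. Without the library that resembles duodenum it fell from 2.48 ± 1.70 to 0.138 ± 0.0877 (-4.13 ± 0.80, adjusted p = 0.0241, 5 lactating libraries). Aqp1 fell from 345 ± 40.2 to 151 ± 38.7 CPM (-1.19 ± 0.16, adjusted p = 0.00275; -1.13 ± 0.16 without that library). Slc19a3 rose from 1.37 ± 0.619 to 5.62 ± 2.43 CPM (2.03 ± 0.35, adjusted p = 0.0222; 1.83 ± 0.35 without). Slc19a1, a folate transporter, rose by 1.15 ± 0.25 (0.88 ± 0.21 without) and the monooxygenase gene Fmo1 by 1.41 ± 0.23 (1.54 ± 0.19 without). Among the other named genes, Gsdmc3 changed by -3.01 ± 0.65 (-2.78 ± 0.64 without), Tmem117 by -1.40 ± 0.23 (-1.25 ± 0.20), and Srd5a2, a steroid reductase, by -1.56 ± 0.31 (-1.39 ± 0.29). The amino acid transporter Slc6a20a changed by -1.04 ± 0.22 (-1.19 ± 0.22 without) and Anxa13 by -0.89 ± 0.11 (-0.84), and Prom1 of the stem cell list rose by 0.69 ± 0.12 (0.70 ± 0.12).

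Without that library, the zinc importer Slc39a4 also passed the test, rising from 379 ± 54.6 to 659 ± 172 CPM (0.80 ± 0.15, adjusted p = 0.0247). So did Acta1 (2.97 ± 0.58), Slc30a10 (0.59 ± 0.13), Gsdmc2 (-2.16 ± 0.52) and Gsdmc4 (-1.97 ± 0.47). Gsdmc2 was at 146 CPM in virgin female jejunum 5 and at 23.5 to 25.5 in the other virgin females, so its fold rests in large part on that library. Ribosomal protein genes then fell in 24 of 76 members and rose in none (65 over the list alone; median -0.26; camera adjusted p = 6.57e-37, and adjusted p = 0.530 with an estimated correlation). Rps12 changed by -0.39 ± 0.08 and Rpl5 by -0.37 ± 0.06. As labelled, 0 of the 76 were called by edgeR (22 lower over the list alone; median -0.19; 1.24e-18, and adjusted p = 0.694 with an estimated correlation). Slc5a4a was at 266 ± 66.1 CPM in 5 lactating and 158 ± 36.4 in virgin libraries (0.75 ± 0.22, adjusted p = 0.0985). Slc5a1 (0.21 ± 0.18, adjusted p = 0.642), Mki67 (0.07 ± 0.16, adjusted p = 0.893) and Lgr5 (0.41 ± 0.24, adjusted p = 0.449) also fell short of the threshold. Cell cycle genes, as labelled, had 0 of 39 called by edgeR (1 up and 1 down over the list alone) and a median of 0.33 (5.90e-08, and adjusted p = 0.694 with an estimated correlation). Without the library that resembles duodenum 0 were called (0 over the list alone), with a median of 0.21 (1.02e-04, and adjusted p = 0.873 with an estimated correlation). That library had 0.198% of its gene reads in these genes. B and plasma cell genes had 0 of 9 called (7 higher over the list alone; 1.11e-04, and adjusted p = 0.694 with an estimated correlation), and 0 over the list alone without that library. Endothelial genes had 0 of 17 (1 higher over the list alone; 4.16e-06, and adjusted p = 0.694 with an estimated correlation), and without that library 0 (1; 2.81e-05, 0.857). Fibroblast genes had 0 of 27 (0 over the list alone; 3.10e-06, and adjusted p = 0.716 with an estimated correlation), and without it 0 (0; 1.12e-05, 0.873). Peptide transport had 1 of 24 lower (1 over the list alone; 4.49e-05, and adjusted p = 0.694 with an estimated correlation), and without it 1 (3; 0.00521, 0.873).

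**Figure D4:**
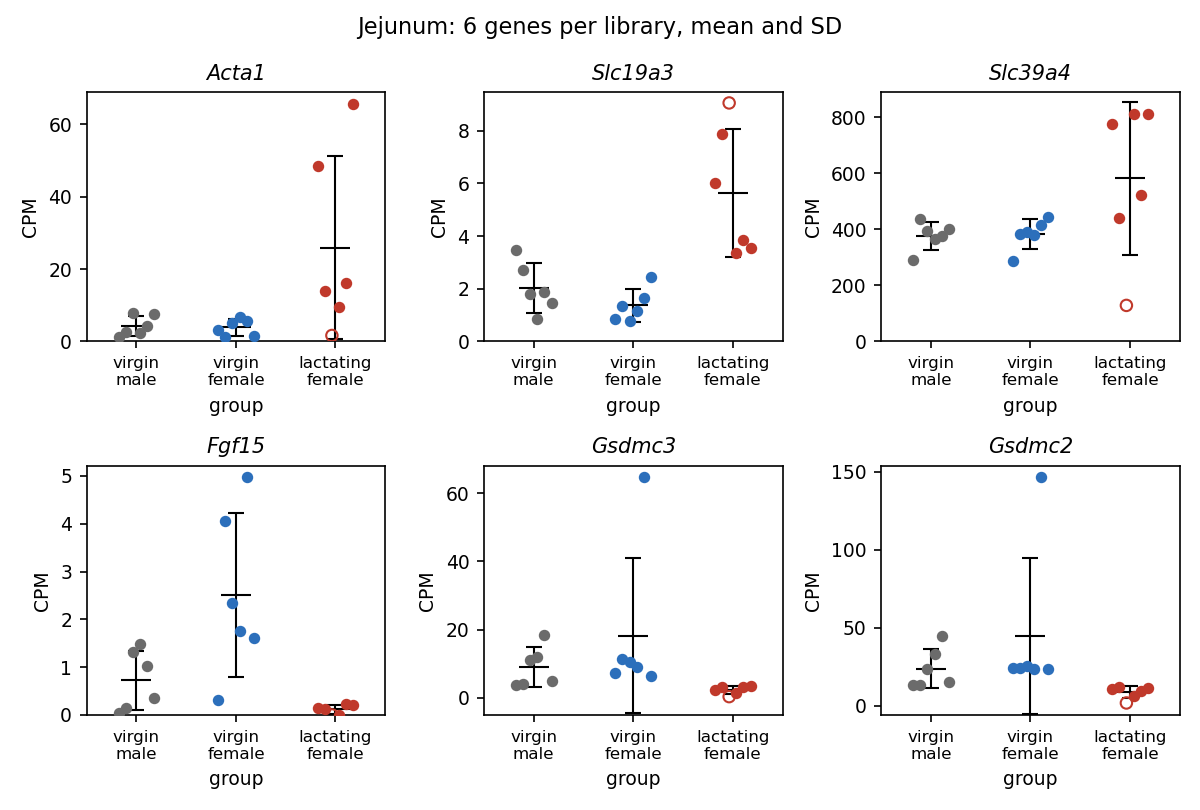
CPM of 6 genes in the jejunum of lactating females, virgin females and virgin males; points are libraries, bars are the mean ± SD of 6, and the open circle is the library labelled lactating female jejunum 3. Slc19a3 averaged 5.62 CPM in lactating and 1.37 in virgin females, and Fgf15 0.117 and 2.51.

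As labelled, edgeR called 68 of 14761 jejunum genes, 18 higher and 50 lower in lactation (35 and 39 with library totals alone); without the library that resembles duodenum it called 194, 51 higher and 143 lower. Leaving out 1 library took the count as labelled to 8, 41, 182 or 9 without lactating female jejunum 2, 4, 5 or 6. It took it to 10, 25, 38, 5 or 15 without virgin female jejunum 1, 2, 3, 5 or 6. Of the 23 called genes named, 2 kept their call in every such fit, Aqp1 and Anxa13; Fgf15 lost it in 3 of 12, Slc19a3 in 3, Slc19a1 in 10, Gsdmc3 and Slc6a20a in 9, Srd5a2 in 7, Tmem117 and Prom1 in 2 and Fmo1 in 1. Gsdmc3 was at 64.7 CPM in virgin female jejunum 5 and at 6.46 to 11.3 in the other virgin females. Between jejunum without that library and ileum, 8 genes were higher in lactation in both where 0.637 would be shared by independent lists (Fisher's exact p = 2.03e-07), among them Slc39a4, Acta1, Slc30a10 and Rtn4r. Another 7 were lower in both where 1.29 would be shared (3.07e-04), among them the 3 gasdermin genes, Srd5a2 and Cldn8. Zbed6 and Ugcg were lower in jejunum and higher in ileum, where 1.78 would be shared (Fisher's exact p = 0.70), and 0 genes went the opposite way (0.459). As labelled, 2 and 2 were shared (Fisher's exact p = 0.0194 and 0.0719). Fisher's test takes genes as independent, which does not hold for genes that vary together, as the 3 neighbouring gasdermin genes may. The labels also do not say whether both sections came from the same animals. These p-values may therefore be too small. Without that library, the log2 fold changes of jejunum and ileum correlated at 0.156 over the 14594 genes tested in both.

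In the duodenum, no gene passed the test for lactation with all libraries as labelled. The largest differences among the genes named in every comparison were those of calcium uptake. In the 5 lactating libraries other than the liver-like one, Trpv6, the apical calcium channel, was at 63.0 ± 78.0 CPM, and in 6 virgin female libraries at 2.07 ± 4.62 (4.87 ± 1.23, adjusted p = 0.181 by edgeR). S100g was at 458 ± 162 and 71.6 ± 85.9 (2.68 ± 0.77, adjusted p = 0.246). The list of calcium and phosphate transport and vitamin D targets had 0 of 14 called (4 higher over the list alone, camera adjusted p = 4.75e-04, adjusted p = 0.11 with an estimated correlation, fry adjusted p = 0.0119). The iron and trace metal list had 0 of 19 called (9 higher over the list alone; 3.01e-06, adjusted p = 0.194 with an estimated correlation, fry 0.0454). Its ferritin gene Ftl1 had a log2 fold change of 0.46 (adjusted p = 0.251). Cholesterol synthesis had 0 of 25 (10 higher over the list alone; median 0.33; 2.34e-11, and adjusted p = 0.269 with an estimated correlation). Adipose genes had 0 of 13 (1 higher and 9 lower over the list alone; 3.31e-05, and adjusted p = 0.324 with an estimated correlation). Exocrine pancreas genes had 0 of 25 (0 over the list alone; median -0.38; 2.08e-09, and adjusted p = 0.705 with an estimated correlation). The pancreas genes, at 0.143% to 0.414% of gene reads in virgin female jejunum, took 0.193% to 2.27% in these 5 libraries. Pdx1, which falls along the gut, was at 28.8 to 75.4 CPM in them and at 18.1 to 71.1 in virgin female duodenum. Among virgins the calcium genes were high where Pdx1 was: female duodenum 2 had 71.1 CPM of Pdx1, 251 of S100g and 11.8 of Trpv6, and male duodenum 3 had 72.3, 455 and 8.99. The other virgin females had at most 33.0 of Pdx1 and 64.5 of S100g. Lactating female duodenum 6 had 28.8 of Pdx1 with 458 of S100g and 26.6 of Trpv6. The lactating mean of Trpv6 rests in large part on lactating female duodenum 4, at 174, where the rest of these 5 had 17.8 to 47.5. Slc5a4a (0.73 ± 0.27, adjusted p = 0.427), Slc5a1 (0.18 ± 0.22, adjusted p = 0.888) and Mki67 (-0.28 ± 0.29, adjusted p = 0.851) did not pass.

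As labelled, edgeR called 0 of 15019 genes, with 1635 at an unadjusted p under 0.05. DESeq2 called 27 and limma-voom 0. In 1 fit of all 54 libraries edgeR called 1407, 1276 higher and 131 lower. Most of these calls depend on the 2 libraries in doubt, as 1 fit of the other 52 called 127, 97 higher and 30 lower. Without the liver-like library edgeR called 1, the cytochrome P450 gene Cyp2d34 (7.04 ± 0.70, adjusted p = 1.20e-04). It was at 13.3 ± 11.9 CPM in 5 lactating and 0.0895 ± 0.109 in 6 virgin libraries. Lactating female duodenum 6 had 34.4 CPM of it, and the rest of the 5 had 2.59 to 12.8. With the liver-like library included, cholesterol synthesis genes stood at a median of 1.86 (23 of 25 higher over the list alone, camera adjusted p = 8.08e-13, and adjusted p = 0.508 with an estimated correlation). The stem cell list had a median of -0.35, a mean of 0.10 and a call as lower (0.00484, and adjusted p = 0.529 with an estimated correlation).

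Whether lactation acted differently along the gut was tested directly. Between ileum and duodenum 8 of 15571 genes differed by edgeR. For 5 the signed log2 effect was higher in the ileum than in the duodenum, which also holds where a gene is lower in the duodenum. These were Zbed6, a transcription factor gene (4.33 ± 0.54, adjusted p = 4.42e-05), Nbeal1 (1.23 ± 0.25), Lnpep (1.18 ± 0.24), Lmbrd2 (2.09 ± 0.41) and Zfp369 (2.26). Zbed6 had opposite signs in the sections, at 1.89 in the ileum (adjusted p = 0.00681) and -2.44 in the duodenum (adjusted p = 0.186). The other 3 had the higher signed effect in the duodenum. They were Cyp2d34 (-7.32 ± 1.20, adjusted p = 0.00548), Ggh, which trims folate (-1.40 ± 0.26, adjusted p = 0.0312), and Notum, an inhibitor of Wnt signals (-4.73 ± 0.96, adjusted p = 0.0499). Between jejunum and duodenum edgeR found 0, with 1543 at an unadjusted p under 0.05 (DESeq2 7, limma-voom 0), and between ileum and jejunum 0, with 785 (DESeq2 5, limma-voom 0). Without the 2 libraries in doubt 2 of these lost their call: -3.07, adjusted p = 0.0606 (Notum, whose lactation effect differs, ileum against duodenum) and 1.13, adjusted p = 0.0522 (Nbeal1, whose lactation effect differs, ileum against duodenum). The test then found 11 genes between ileum and duodenum, among them Sult1c2 (-2.02 ± 0.40) and Oxct1, of ketone body use (-0.84 ± 0.15). Between ileum and jejunum it then found 4: Ttll2 (2.50 ± 0.40), Zbed6 (2.87 ± 0.51), Slc25a15 (0.83 ± 0.16) and Tmem117 (adjusted p = 0.0485). Slc5a4a was in none of these sets, so its call in the ileum is not shown to differ from the other sections. Scaled by library totals alone, 2 genes differed between ileum and duodenum.

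Virgin females were compared with virgin males to ask which differences follow sex. Xist, the RNA of the inactive X chromosome, was at 290 ± 27.2 CPM in female and 0.143 ± 0.101 in male jejunum (10.95 ± 0.21). The Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty had no read in virgin females of any section. In the ileum they were at least 2000-fold, 2210-fold, 1280-fold and 900-fold lower. Fgf15 was higher in female ileum, at 42.8 ± 40.3 against 1.11 ± 0.672 CPM (n = 6 each, log2 fold change 5.26 ± 0.82, adjusted p = 0.00526 by edgeR). Virgin female ileum 5 was at 118 CPM and the other virgin females at 3.57 to 53.0. In the jejunum Fgf15 was at 2.51 ± 1.72 and 0.725 ± 0.621 (1.78 ± 0.63, adjusted p = 0.830). Car12, a carbonic anhydrase gene, was at 47.8 ± 8.34 in female and 26.8 ± 3.01 CPM in male ileum (0.83 ± 0.13, adjusted p = 0.00461). Pde9a was higher in females (0.75 ± 0.13), and the complement gene C7 (-0.84 ± 0.14) and Stc2 (-0.90 ± 0.17) were lower. Leaving out 1 library, Pde9a lost its call in 7 of 12 fits (highest adjusted p = 0.0945) and Stc2 in 8 (0.124), while Fgf15, Car12 and C7 lost it in 0. The X-linked Kdm6a and Eif2s3x were higher in female jejunum (0.57 ± 0.08 and 0.55 ± 0.07) and ileum (0.94 ± 0.10 and 0.58 ± 0.08). Zbed6 was lower in female jejunum, at 5.08 ± 0.908 against 17.9 ± 6.96 CPM (-1.82 ± 0.21, adjusted p = 1.41e-04).

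Sex-linked genes were called in 1 up and 4 down of 9 in the duodenum (4 and 4 over the list alone; camera adjusted p = 1.99e-15, and adjusted p = 3.88e-05 with an estimated correlation). In the jejunum they were called in 4 and 4 (4 and 4 over the list alone; 5.25e-10, and adjusted p = 2.56e-04 with an estimated correlation), and in the ileum in 3 and 4 (5 and 4 over the list alone; 1.61e-06, and adjusted p = 0.0829 with an estimated correlation). Their medians (0.09, 0.06 and 0.31) were above 0 while their means (-4.33, -4.26 and -4.18) and the test pointed to lower in females, since Y-linked genes set the mean. These fitted values depend on the prior count where females had no reads. Bile acid genes in the ileum were higher in 1 of 11 (6 over the list alone; 8.59e-06, and adjusted p = 0.266 with an estimated correlation). Paneth cell genes had 0 of 18 called by edgeR (4 higher over the list alone; median 0.82; 1.10e-10, and adjusted p = 0.488 with an estimated correlation). In total edgeR called 5 of 15019 genes in the duodenum, 10 of 14761 in the jejunum and 15 of 15106 in the ileum. Without virgin female ileum 2 the ileum count was 90, and without virgin male ileum 1 it was 61. The sex effect differed between sections for 12 of 15570 genes, with Zbed6 at the lowest adjusted p (2.70e-04).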

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

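Of the tests below, those on the 2 libraries that differ from their labelled section were chosen after their values were seen; the tests on the lactating ileum and on Zbed6 were chosen before theirs. Chance sets about 1 in 20 groups of samples apart by the gap measure used here, and 20 of 278 groups had a sample that far from the others.

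The library labelled lactating female duodenum 3 and that labelled lactating female jejunum 3 differed from their labelled section. In the first, 15791 genes had reads (17298 to 17749 in the rest of its group) and the top 20 genes took 28.7% of gene reads (9.82% to 12.6%). Liver mixed into duodenum is argued against by the gut genes: 54 members of the sugar, peptide and villus tip lists stood at a median of 1.44% of the other lactating duodenum libraries, too low for a part share of gut tissue. An exchange of labels between these 2 libraries is argued against by the first library's correlation with the jejunum profile, 0.660 where the other jejunum libraries reach 0.981 or more. Duodenal tissue in the jejunum tube, tested as the library's place between both sections (78.1% of the way to the duodenum), stays open and may account for its 21.2 CPM of Slc5a4b (106 to 224 in its group) and 9.47 CPM of Tmem117 (20 to 30.9 in its group); the design gives no biological group to test.

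Genes that are abundant in the jejunum rose in the lactating ileum. Jejunal tissue mixed into those samples is argued against: Slc5a4a gained 16.4% of its jejunum level, while 28 other genes with a large jejunum to ileum ratio gained a median of 0.383% and Lct 0.0243%. Sampling nearer to the jejunum could also raise such genes. A score of 223 genes higher in male jejunum was 0.57 ± 0.13 in lactating and 0.18 ± 0.27 in virgin ileum (exact permutation p = 0.00649, 2-sided, n = 6 each; 28 called higher and 0 lower), but 87 genes higher in male ileum moved by only -0.04 (exact p = 0.519; 3 higher and 4 lower). The difference of both scores separated the groups (exact p = 0.00866), but through the jejunum-high genes that make up the pattern, so it lends a shifted sampling site no support of its own; that explanation and an effect of lactation itself cannot be told apart here.

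Zbed6 was called in the differences between sections of both the lactation effect and the sex effect. Of the 17 other genes named in those differences, 11 had a correlation above 0.5 with Zbed6 across 52 libraries, as deviations from the group means. The share of all genes above 0.5 was not counted, so these 11 are not shown to be a group apart. The mean of these and Zbed6 did not follow the log2 of gene reads (r = -0.0303, permutation p = 0.833; -0.0719 without the 2 farthest libraries; rho = 0.00137, p = 0.994), which argues against library size; the percent of reads in no gene feature stays open, at r = 0.172 (p = 0.217; 0.257 without the 2 farthest; rho = 0.0108, p = 0.940). It did follow a score of long against short transcripts (r = 0.706, p = 1e-05, the smallest that the permutations give, adjusted p = 3e-05 over these 3 relations; rho = 0.496, p = 5e-05, likewise the smallest; r = 0.549 without the 2 farthest libraries). Uneven RNA degradation or fragment selection is therefore a candidate explanation: the longest transcripts of Nbeal1 and Lnpep have 15731 and 12052 bases where the median gene has 3293, though that of Zfp369 has 2911, and Slc26a2 and Uvssa, with 7814 and 7326, followed Zbed6 less (r = 0.372 and 0.196). The score did not differ by group past adjustment (virgin females less males in the duodenum -0.18, exact p = 0.0260, adjusted 0.156), and sex or lactation as the cause was not tested apart from it.

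Lactation effects differed between ileum and duodenum for 8 genes, as log2 of the ileum effect less that in the duodenum: Cyp2d34 -7.32, Nbeal1 1.23, Zbed6 4.33, Lnpep 1.18, Ggh -1.40, Notum -4.73, Zfp369 2.26 and Lmbrd2 2.09. Without the 2 libraries in doubt Notum and Nbeal1 lost their call; 26 of 100 random splits of the samples gave as many genes as the 8 (highest 256), so chance was not excluded. The effect of sex differed between sections for Slc26a2 (adjusted p = 0.0204), D830031N03Rik (0.0392), Cbl (0.00332), Zbed6 (2.70e-04), Shprh (0.0446), Rnase4 (0.0392), Uvssa (0.0204), Plag1 (0.0392), Pdpr (0.0212), Zfp369 (0.00418), Elk4 (0.0204) and Gdap10 (0.0359); 5 of 100 splits gave as many (highest 317), so chance was not excluded here either.

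Other samples stood far from their group, given as the sample's value and, in brackets, the range of the rest. CPM here was scaled over all 54 libraries, so it differs from the values in the fits above. Virgin male ileum 3 had 18479722 gene reads (20895854 to 22114563). Virgin male jejunum 2 had 14.4% of gene reads in its top 20 genes (11.1% to 12.3%) and 65.1 CPM of Ddx3y (52.7 to 56.6). Virgin female ileum 2, whose removal raised the lactation count of the ileum to 1184, had 12.2% in its top 20 genes (9.0% to 10.1%) and 19.7 CPM of Eif2s3x (26.0 to 28.9); its score of long against short transcripts was 0.48, where the rest of its group had 1.38 or more. Trpv6 was at 11.1 CPM in virgin female duodenum 2 (0.0775 to 0.409). Ctrb1 was at 0.572 CPM in virgin female duodenum 3 (157 to 2140). Virgin female jejunum 3 had 8.75 CPM of Defa32 (0.233 to 1.06), 14 of Slc10a2 (2.26 to 4.35) and 13.5 of Fabp6 (0.23 to 1.3). Gsdmc3 was at 71.9 CPM in virgin female jejunum 5 (7.28 to 12.3). Alppl2 was at 0.649 CPM in lactating female jejunum 1 (1.54 to 2.03). Xist was at 327 CPM in lactating female jejunum 3 (254 to 279). Mki67 was at 111 CPM in lactating female ileum 3 (128 to 137). Flvcr2 was at 17.8 CPM in lactating female ileum 4 (8.64 to 11). The symbol ccdc198 was at 25.4 CPM in virgin female ileum 6 (36.4 to 43.6).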

How the results depend on the processing

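The tests without the 2 libraries in doubt, the single fit of the other 52, and the estimated correlation for sections were chosen after seeing the data. The cause was not tested for any change below, except that fewer libraries, a fold limit or another set of genes are changes by construction. Genes changed by lactation in the duodenum (0 by edgeR, 1635 at unadjusted p under 0.05) numbered 27 with DESeq2, 1 with replicate numbers as blocks, 1407 with all 54 libraries in one fit, 1 without the libraries in doubt and 127 in the fit of 52. In the jejunum (68) they numbered 511 with DESeq2, 45 with no count filter, 21 with blocks, 4 from the 2 groups alone, 42 with all 54 libraries, 16 at a log2 change of at least 1, 194 without the libraries in doubt and 138 in the fit of 52. In the ileum (327) they numbered 575 with library totals, 891 with DESeq2, 161 from the 2 groups alone, 10 with all 54 libraries, 52 at a log2 change of at least 1 and 152 in the fit of 52. Genes changed by sex in the duodenum (5) became 2 with blocks, 8 with all 54 libraries and 10 in the fit of 52; in the jejunum (10), 23 with DESeq2; in the ileum (15), 68 with DESeq2, 8 from the 2 groups alone and 7 at a log2 change of at least 1. That fold limit left 1354, 1932 and 2453 genes between jejunum and duodenum, ileum and jejunum, and ileum and duodenum. Genes whose lactation effect differed numbered 7 with DESeq2 between jejunum and duodenum (0 by edgeR); 5 with DESeq2 and 4 without the libraries in doubt between ileum and jejunum (0 by edgeR); and, between ileum and duodenum (8), 2 with library totals, 37 with DESeq2, 4 with voom, 5 with no count filter and 2 with blocks. Those whose sex effect differed (12) became 28 with DESeq2, 5 with voom and 7 with blocks. Lists called for lactation fell from 24 to 0 with an estimated correlation and 0 with fry in the duodenum, 15 to 0 and 0 in the jejunum, and 17 to 0 and 4 in the ileum. For sex they went from 13 to 1 and 1, 9 to 1 and 1, and 21 to 0 and 1 in the same order, and for sections from 56 to 0 with an estimated correlation. Leaving out 1 library gave 0 to 2 genes for lactation in the duodenum (2 without lactating 2, 1 without lactating 3), 5 to 194 in the jejunum (lactating 2, 3, 4, 5 and 6: 8, 194, 41, 182 and 9; virgin 1, 2, 3, 5 and 6: 10, 25, 38, 5 and 15), 112 to 1184 in the ileum (lactating 1, 3 and 6: 159, 205 and 173; virgin 1, 2, 3 and 5: 112, 1184, 143 and 196), and 10 to 90 for sex in the ileum (61 without male 1, 90 without virgin female 2); the counts for sex elsewhere and for sections stayed within 1.5 times. Log2 changes that reversed were past no threshold: -1.24 with voom (Slc5a4a, lactating against virgin females, duodenum), 0.18 without the libraries in doubt (Slc5a1, lactating against virgin females, duodenum), -0.0104 with library totals (Mki67, lactating against virgin females, ileum), -0.00703 with library totals, -0.0285 with voom and -0.0125 with all 54 libraries (Slc5a1, virgin females against virgin males, duodenum), -0.000505 with median-of-ratios factors, -0.0437 with library totals, -0.00133 with DESeq2, -0.000267 with no filter, -0.00285 from the 2 groups alone and -0.00802 with all 54 libraries (Lgr5, virgin females against virgin males, ileum), 0.00147 with median-of-ratios factors and with DESeq2 and 0.00362 with all 54 libraries (Olfm4, jejunum against duodenum in virgin females), and 0.0531 with voom (Oxct1, whose lactation effect differs, ileum against duodenum). Of 80 named lactation calls, 79 were kept with median-of-ratios factors, 69 with library totals, 80 with DESeq2, 74 with voom, 73 with no filter, 55 with blocks, 37 of 79 from the 2 groups alone and 13 with all 54 libraries; of 26 named sex calls, 19 to 26 were kept. The blocks assume that numbers pair the samples, which the labels do not state and the values do not show: over 15 pairs of groups, same-number correlations ran from -0.557 to 0.568, and 0 pairs had every correlation above 0.1. Depth left genes under the minimum count untested, and replicate spread limited small changes: in simulated data without the 2 libraries in doubt (the fits as labelled were not simulated), 1.5-fold changes were recovered for 37.3%, 59.7% and 62.7% of genes in duodenum, jejunum and ileum, and 4-fold changes for 97.0%, 98.5% and 98.5%. The simulated genes varied independently of one another, so the real fits, where libraries differ in many genes at once, may recover less.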

Other observations

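The tests without the 2 libraries in doubt and those with an estimated correlation for sections were chosen after seeing the data; the others below were not.

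Several groups of genes differed along the intestine of virgin females beyond those described above, with all libraries as labelled and 6 samples per section. From duodenum to jejunum, 10 of 11 B and plasma cell genes fell (11 adjusted over the list alone; camera adjusted p = 0.0152, 0.649 with an estimated correlation), as did 17 of 22 T cell genes (19; 3.27e-04, 0.649), 12 of 17 endothelial genes (13; 3.27e-04, 0.649) and 4 of 5 Brunner gland and stomach genes (4; 0.00163, 0.155). Among 39 cell cycle genes 19 fell and 1 rose (21 and 1; 1.85e-04, 0.649). Villus tip genes rose for 8 of 13 and fell for 2 (9 and 2; 0.00163, 0.626), and genes of endoplasmic reticulum stress rose for 10 of 25 and fell for 1 (10 and 1; 0.0075, 0.648). The enteroendocrine list did not pass the test (0.0887, 0.649), with 8 of 23 genes lower and 2 higher (8 and 2 over the list alone); Cck went from 46.9 ± 11.7 to 8.28 ± 3.39 CPM (log2 change -2.51 ± 0.24 SE, adjusted p = 2.55e-07, groups not overlapping).

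From jejunum to ileum, 12 of 13 villus tip genes fell (12; 4.66e-06, 0.335), 15 of 22 fatty acid oxidation genes fell and 1 rose (15 and 1; 9.49e-06, 0.680), 12 of 21 macrophage genes rose (14; 1.98e-04, 0.680), 16 of 28 ribosome biogenesis genes rose (16; 0.00104, 0.724), and 8 of 21 enteric neuron and glia genes rose while 1 fell (8 and 1; 0.0172, 0.786). Between ileum and duodenum, 21 of 34 interferon response genes were lower (21; 1.89e-05, 0.649), 10 of 18 smooth muscle genes were higher (11; 8.19e-04, 0.729), and 12 of 20 antimicrobial genes were higher with 5 lower (12 and 5; 0.00662, 0.496). Saa1 stood at 284 ± 165 CPM in ileum and 0.249 ± 0.336 in duodenum (log2 change 10.13 ± 0.99 SE, adjusted p = 7.1e-08, groups not overlapping).

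Each count was set against 100 splits of the same samples into groups of the same sizes, the real one included. Between sections, no other split reached the count: jejunum and duodenum 5635 (highest other 2217), ileum and jejunum 7271 (4982), ileum and duodenum 7130 (4333). Nor did any reach the lactation count in the jejunum (68, 26), the ileum (327, 65) or the jejunum without the libraries in doubt (194, 49). In each case only the labelled split was as large, 1 of 100, the smallest share that 100 splits can give. In the same sections, splits of virgin females and males called up to 859 genes in the jejunum and 376 in the ileum. A structure of the samples other than lactation is therefore not excluded. In the duodenum the lactation count of 0 by edgeR (1635 at unadjusted p under 0.05, 27 with DESeq2) is reached by any split (100 of 100, highest other 0), so the splits decide nothing there. For sex, 1 of 100 gave as many in the duodenum (5, highest other 0) and 2 in the jejunum (10, highest other 859). The duodenum calls were Xist, Ddx3y, Eif2s3y, Kdm5d and Uty, and most jejunum calls were sex-linked too. Such genes differ by chromosome content, so the labels had to stand out, and these splits decide nothing on other effects of sex. In the ileum 5 of 100 gave as many (15, highest other 376), so chance was not excluded. The splits with 859 and 376 genes call several times the real count and point to a structure of the samples other than sex.

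For differences in the lactation effect, the splits decide nothing where the real count was 0, as 100 of 100 reach it: jejunum and duodenum (0 by edgeR, 1543 at unadjusted p under 0.05, 7 with DESeq2; highest other 97) and ileum and jejunum (0 by edgeR, 785 unadjusted, 5 with DESeq2; highest other 0). Between ileum and duodenum 26 of 100 gave as many (8; 256), or 5 without the libraries in doubt (11; 594), so chance was not excluded. There 20 splits called more than 3 times the real count, which points to a structure of the samples. For the difference in the sex effect, 5 of 100 gave as many (12; 317), so chance was not excluded, and the split with 317 genes points the same way. Zbed6 is in both sets of genes.

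For lists, 4 of 100 splits gave as many for lactation in the duodenum (24, highest other 25) and 3 of 100 for sections (56, highest other 57). The duodenum fit holds the library with liver transcripts (19 lists without the libraries in doubt, a count not set against splits). With all libraries as labelled, an estimated correlation or fry called 0 lists there. The fry values under 0.05 given above for the calcium list and the iron and trace metal list are from the fit without the liver-like library. Fry values of other lists are not given. For lactation in the duodenum and for sections, a random split called more lists than the labels, so chance is not taken as excluded. Nor was chance excluded for lactation in the jejunum (15, highest other 24, 57 of 100) or without the libraries in doubt there (16, 20, 34 of 100). The same holds for lactation in the ileum (17, 23, 24 of 100). For sex it was not excluded in the duodenum (13, 18, 29 of 100), jejunum (9, 19, 91 of 100) and ileum (21, 22, 6 of 100). The other splits called a median of 17 lists for lactation in the duodenum and 45 for sections, so in these comparisons groups drawn at random also gave many list calls at the preset correlation of 0.01; which lists they were was not counted.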
